A study of Mus musculus with 50 samples.

How the data were processed

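Gene expression was measured by RNA sequencing of total RNA from J1 mouse ES cells: wild type cells and the NSD1-/- lines labelled KO1 and KO2, with 2 libraries in each group. The labels give the sample groups and the replicate numbers. They do not say how either line was made or whether the libraries of a group came from separate cultures. The series holds 50 samples, and the 44 others, from chromatin assays, were not analysed here.

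The values are raw counts per gene, deposited as a table per library, with no normalization. Per the file headers, the authors counted paired fragments over exons, summarised by gene, with featureCounts 2.0.1, a strand setting of 1 and the GENCODE mouse version 1 annotation on mm9. Per the submitters' processing notes, Trim Galore 0.6.4, STAR 2.5.4b, Bowtie2, GATK 4.1.4.0, featureCounts 2.0.0 and bedtools 2.92.2 were used, with no role given for each. Per the labels' protocols, RNA was purified with a column kit and libraries followed standard Illumina protocols, and whether the kit marks strand is not given in the sources used here. The spans and strands of all 37310 genes in the tables equalled those of the GENCODE version 1 annotation, so coordinates are mm9, 1-based, as the tables give them.

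A strand setting of 1 keeps only fragments whose first read lies on the strand of the gene. Abundant genes had few counts and genes opposite them had many, so the counts were read as fragments of the strand opposite to the counted gene. For each counted gene, the gene opposite it was taken as the gene on the other strand with the largest exon overlap of at least 50 bases, found with bedtools 2.31.1. The values are given for the counted gene, with the gene opposite it. Where no annotated gene lies opposite, the tables do not tell whether the fragments came from the counted gene's own transcripts or from an unannotated transcript.

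Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr by group with a minimum count of 10, TMM scaling, and a quasi-likelihood fit with robust dispersions over all 6 libraries, with a mean for each of the 3 groups and no replicate term. The fit left 3 residual degrees of freedom, and the common biological coefficient of variation was 4.46%. The filter left 5034 genes. The contrasts were the mean of KO1 and KO2 against wild type, each line against wild type, and KO1 against KO2. A gene was called where the Benjamini-Hochberg adjusted p over all tested genes was under 0.05. Errors given with a log2 fold change are standard errors of the fit, and errors given with CPM, counts scaled to the effective library size, are SDs over libraries, 2 per group or 4 for the knockout lines together. Where a group held 1 to 3 counts in all, the ratio of summed counts is given with an exact 95% interval, and where it held 0, a lower bound against 3 counts over the group. These intervals and bounds cover counting error only.

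The design, the tests, 25 gene lists and the rule for named genes were fixed before the data were examined. The rule took the 12 largest changes each way in the knockout lines together among called genes with a mean of at least 5 CPM in the highest group and all 4 knockout libraries beyond both wild type libraries. It took the 5 largest each way between KO1 and KO2 by the same criteria, and left out predicted genes and small RNA genes. It also took Nsd1, Whsc1 (Nsd2), Whsc1l1 (Nsd3), Hdac1 and Hdac2, and from each list up to 4 called members or, where none was called, up to 2 of the most abundant. Some of the genes so taken are not reported here. Since that rule does not look at the opposite strand, up to 10 called genes each way with a named protein-coding gene opposite, of any name, were added after their values were seen.

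The gene lists were tested with camera in limma 3.58.1 with an inter-gene correlation of 0.01, with camera with an estimated correlation, and with fry, where at least 5 members were measured. The lists were tested by the symbol of the counted gene, as planned, and also by the symbol of the gene opposite, a choice made after the counts were seen. Shifts of whole chromosomes were computed as the median log2 fold change of the tested genes on a chromosome minus that of all tested genes. The tests of these shifts with camera were chosen after the shifts were seen. Because both lines share the wild type libraries, 40 simulations of unchanged groups gave the values that shared controls produce on their own.

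The steps were tested on simulated counts drawn from the means and library sizes of the real libraries, with 4719 genes passing the filter there. In the simulated comparison of the lines together with wild type, 66% of 100 genes planted with a log2 change of 1 and 91% of 100 with a change of 2 were called, and 5 unchanged genes were called. The shares were 58% and 86% for KO1, and 52% and 88% for KO2. Between KO1 and KO2, where none was planted, 1 gene was called. The alternatives tried were DESeq2 size factors, no filter, a mean CPM of at least 1, DESeq2 1.42.0 (Wald test), limma-voom, a replicate block, leaving out each library, a test against a log2 change of 0.5 (glmTreat), the knockout libraries as a single group, and the line as a random block. Alternatives chosen after the data were seen left out AY036118, left out chromosomes 6 and 11, kept only genes opposite another gene's exons, or set each line against 1 of the wild type libraries, with the 2 wild type libraries as separate groups in the same edgeR fit. Figures were drawn with matplotlib 3.10.9.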

Results

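J1 cells are a mouse embryonic stem (ES) cell line of the 129S4/SvJae strain, grown here with serum and the cytokine LIF on gelatin. Wild type J1 cells were compared with 2 lines of the genotype NSD1-/-, KO1 and KO2, with 2 RNA libraries per group. NSD1 is a methyltransferase that places H3K36me2, and the title of the series ties it to the histone deacetylase HDAC1 and to acetylation of H3K27 at active enhancers. The comparison asks which genes change expression without NSD1. Total counts were 1203554 and 1237783 in wild type, 1168961 and 1194285 in KO1, and 1150089 and 1285487 in KO2. The median tested gene held 23 to 27 counts per library, so differences in most genes rest on few fragments. No label says that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

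The counts were read as fragments of the strand opposite to each counted gene, from the values that follow. AY036118, a locus on chromosome 17 known to overlap a copy of the ribosomal RNA precursor, took 32.3% to 37.2% of the counts. Apart from it, 89.7% of the counts lay at the 5431 of 37310 genes whose exons overlap an exon on the other strand, and this held for all 50 genes with the highest counts. Actb, which encodes beta-actin, had 104 to 144 counts per library, and the pluripotency factor Pou5f1 had 14 to 23. The ribosomal protein gene Rpl23a had 29 to 46, against 11382 to 18509 for Tlcd1, which overlaps it on the other strand. The RNA-binding protein gene Hnrnpab had 106 to 157, against 8884 to 11141 for Agxt2l2 opposite. All 75 ribosomal protein genes together held at most 0.231% of the counts of a library. Values below are therefore given for the counted gene, at its first mention with any gene opposite it in mm9.

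**Figure D1:**
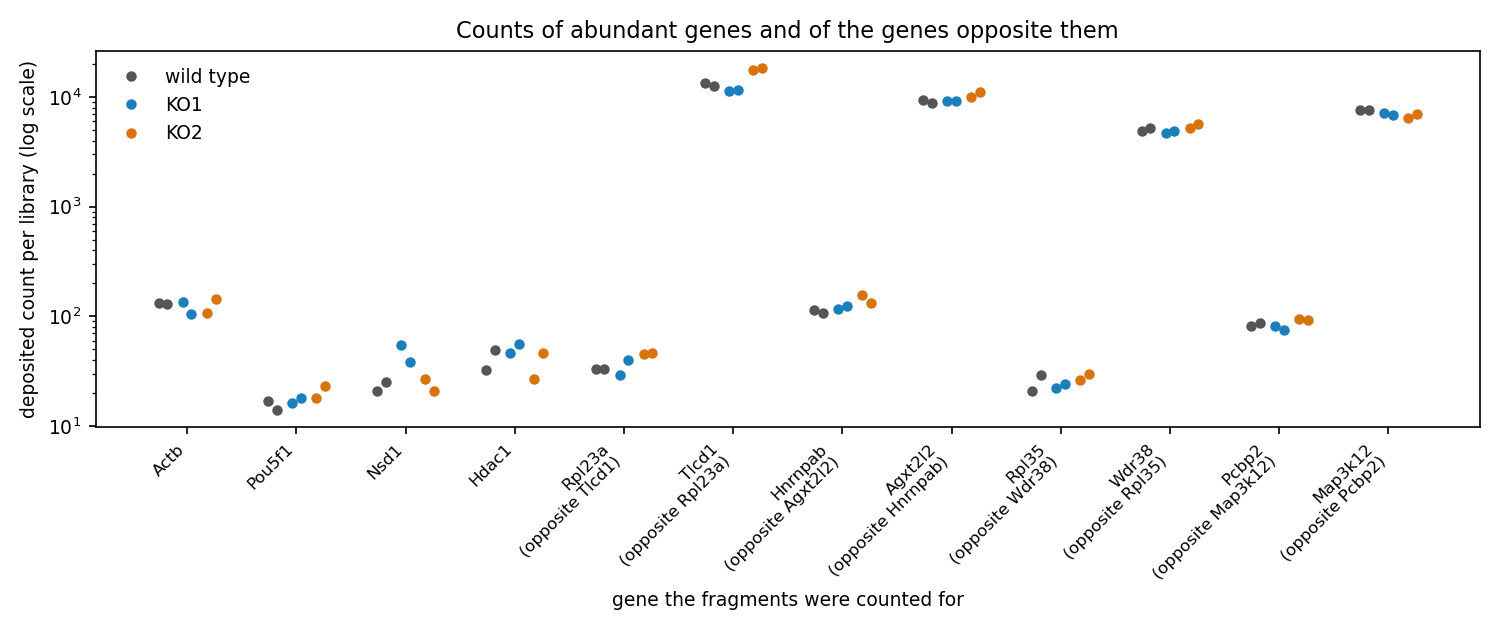
Deposited counts (log scale) of 12 genes in each of the 6 libraries, a point per library, coloured by group. Rpl23a, Hnrnpab, Rpl35 and Pcbp2 lie at 21 to 157 counts, and the genes opposite them, Tlcd1, Agxt2l2, Wdr38 and Map3k12, at 4754 to 18509.

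Nsd1 (chromosome 13, 55311143 to 55419686, plus strand) held 21 and 25 counts in the wild type libraries, 55 and 38 in KO1, and 27 and 21 in KO2. No annotated exon lies opposite Nsd1, and at these counts on that strand the values do not check the loss of Nsd1 that the labels give. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, Nsd1 counts were higher in KO1 (log2 fold change 0.94 ± 0.27, adjusted p 0.0230) and were not called in KO2 (0.05 ± 0.31, adjusted p 0.945) or in the lines together (0.50 ± 0.26, adjusted p 0.301). The related methyltransferase genes Whsc1 (opposite Whsc2) and Whsc1l1 were not called, at 0.07 ± 0.22 and -0.81 ± 0.51, nor was Hdac1, at 0.05 ± 0.22. Hdac2 had 0 to 10 counts and was not tested.

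In the knockout lines together, fragments at Gm17329 (chromosome 11, 94810494 to 94811645), opposite Col1a1, which encodes a chain of type I collagen, fell from 74.1 ± 8.25 CPM in wild type (n = 2) to 2.54 ± 1.22 (n = 4). Fragments at Syn3 (chromosome 10, 85517870 to 85961641), opposite Timp3, an inhibitor of metalloproteinases, fell from 74.0 ± 11.9 to 12.3 ± 3.26 CPM. Grb10 (chromosome 11, 11830511 to 11938686), an imprinted gene for an adaptor of the insulin receptor, rose from 18.9 ± 4.49 to 69.2 ± 14.6 CPM, and E130003G02Rik (chromosome 2, 25146740 to 25154445), opposite the glutamate receptor gene Grin1, rose from 67.3 ± 0.148 to 181 ± 32.8. The log2 fold changes were -4.84 ± 0.30 for Gm17329, -2.60 ± 0.21 for Syn3, 1.86 ± 0.23 for Grb10 and 1.41 ± 0.12 for E130003G02Rik. Their adjusted p were 1.84e-12, 5.32e-10, 1.86e-06 and 1.51e-09 (edgeR's quasi-likelihood test, Benjamini-Hochberg). Gm17329 and E130003G02Rik were chosen after their values were seen.

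Of 5034 tested genes, 137 rose and 196 fell by edgeR's quasi-likelihood test with an adjusted p under 0.05, 43 and 32 of them with a log2 fold change of at least 1 in size. Of those that rose, 55 lie on chromosome 11, which holds 560 tested genes. Of those that fell, 44 lie on chromosome 6, which holds 259. As given below, each of these chromosomes shifted in a single line. Genes opposite another gene's exons were called more often (10.8% of 2474) than the others (2.62%). These rates were not compared at equal abundance. Over all annotated genes, those overlapping an exon on the other strand held a median of 47 counts summed over the libraries, against 0 for the others. DESeq2 called 115 genes, all of them among these 333, the test against a log2 change of 0.5 called 16, and leaving out wild type replicate 1 or 2 gave 213 or 218. A fit that counts the difference between the lines as spread called 6 genes with the knockout libraries as a single group and 5 with the line as a random block. Gm17329, Syn3, E130003G02Rik, Gm16033 (opposite the metalloproteinase gene Adam19, 1.25 ± 0.09) and Gm11175 (opposite Jund, a subunit of AP-1, -0.61 ± 0.05) were called in both of these fits, and Grb10 in the first (adjusted p 0.0175, against 0.110 in the second).

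Among the genes taken by the rule, those that rose also included Adcy9 (2.67 ± 0.40), an adenylate cyclase gene, Acrbp (2.56 ± 0.59), the autoantigen gene Ica1l (1.92 ± 0.53), Prr15l (1.88 ± 0.50) and the tyrosine kinase gene Src (1.76 ± 0.42), none with an annotated exon opposite. Adcy9 stood at 4.31 ± 0.0877 CPM in wild type, 75.9 ± 12.4 in KO1 and 10.2 ± 4.29 in KO2, and was called in KO1 (4.10 ± 0.33, adjusted p 2.27e-10) but not in KO2 (1.23 ± 0.52, adjusted p 0.151). D10Bwg1379e held 3 counts in wild type, and its ratio was 7.0 in KO1 (95% interval 2.10 to 36.5) and 9.93 in KO2 (3.09 to 50.9). With a gene opposite, Rprd1b (2.22 ± 0.50) and RP23-396G1.3 (1.86 ± 0.32), both opposite the transglutaminase gene Tgm2, rose, as did Casp9 (opposite Cela2a, 2.14 ± 0.59), Stx8 (opposite RP23-25D18.6, 1.92 ± 0.54) and Gpr89 (opposite Pdzk1, 1.85 ± 0.57). Their edgeR adjusted p ran from 3.13e-05 for Adcy9 to 0.0480 for Gpr89. In the lines apart, Acrbp, D10Bwg1379e, Rprd1b, RP23-396G1.3, Stx8 and Src passed in both, Ica1l in KO1 (KO2 adjusted p 0.170), and Prr15l, Casp9 and Gpr89 in KO2 (KO1 adjusted p 0.0547, 0.267 and 0.149); the difference between the lines was called for Adcy9 and Casp9. Of these genes, Adcy9 and RP23-396G1.3 were also called by DESeq2, which gave no adjusted p to the others, and none was called by the fits that count the difference between the lines as spread.

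Those that fell included Pcdhb17 (-2.82 ± 0.56), a gene of the beta protocadherin cluster of adhesion proteins, the cytokine gene Il17d (-1.28 ± 0.27), Prkcz (-1.58 ± 0.43), an atypical protein kinase C, the paraspeckle protein gene Pspc1 (-1.26 ± 0.29), the homeobox gene Nkx6-3 (-1.16 ± 0.31) and Prss16 (-1.29 ± 0.36), none with an annotated exon opposite. Foxd1, a forkhead transcription factor gene, stood at 20.7 ± 4.08 CPM in wild type, 1.21 ± 1.72 in KO1 and 11.3 ± 5.47 in KO2; it held 48 counts in wild type and 3 in KO1, a ratio of 16.8 (95% interval 5.40 to 84.1). With a gene opposite, Fez2 (opposite Crim1, -1.81 ± 0.43), Clca6 (opposite Gm16233, -1.67 ± 0.33), Scand1 (opposite 4921517L17Rik, -1.30 ± 0.35) and Nudt16l1 (opposite Gm16861, -1.22 ± 0.36) fell. Their edgeR adjusted p ran from 4.78e-04 for Foxd1 to 0.0362 for Nudt16l1. In the lines apart, Pcdhb17 and Il17d passed in both, Foxd1, Prss16, Pspc1 and Nudt16l1 in KO1 (KO2 adjusted p 0.0794 to 0.278), and Prkcz, Nkx6-3, Fez2, Clca6 and Scand1 in KO2 (KO1 adjusted p 0.0697 to 0.325); the difference between the lines was called for Foxd1 and Clca6. None of these was called by DESeq2, which gave an adjusted p for Il17d (0.0882) and Nkx6-3 (0.209) and none for the others.

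Among called genes with a named protein-coding gene opposite, chosen after their values were seen, Gm15622, opposite the betaine-homocysteine methyltransferase gene Bhmt, rose by 2.32 ± 0.19, from 21.2 ± 5.92 CPM in wild type to 51.8 ± 3.33 in KO1 and 216 ± 5.83 in KO2. Also higher were 1810009N23Rik (opposite Galnt6, 2.24 ± 0.50), 4933431E20Rik (opposite Eps8l3, 1.69 ± 0.38), Fam151a (opposite Acot11, 1.62 ± 0.26) and L3mbtl2 (opposite Chadl, 1.27 ± 0.37). Lower were Gm15726 (opposite Mid1, -1.91 ± 0.48), Gm17443 (opposite the growth factor gene Nrg1, -1.53 ± 0.29), 2700086A05Rik (opposite Hoxa7, -1.40 ± 0.21), Gm7628 (opposite Plxnb1, -1.36 ± 0.31), Gm16263 (opposite the growth factor gene Fgf10, -1.29 ± 0.23), 9930014A18Rik (opposite Fam84b, -1.26 ± 0.23) and Gm11131 (opposite H2-Q4, -1.26 ± 0.33). Their edgeR adjusted p ran from 5.32e-10 for Gm15622 to 0.0322 for L3mbtl2. In the lines apart, Gm16263 and Gm11131 passed in KO1 and not in KO2 (adjusted p 0.0757 and 0.101), and 4933431E20Rik, L3mbtl2, Gm17443 and Gm7628 in KO2 and not in KO1 (adjusted p 0.0617 to 0.209), while the others passed in both. The difference between the lines was called for Gm15622, Gm16263 and Gm17443. DESeq2 called Gm15622, Fam151a, 2700086A05Rik, Gm16263 and 9930014A18Rik in the lines together and gave no adjusted p to the others, and the fits that count the difference between the lines as spread called none of these genes.

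**Figure D2:**
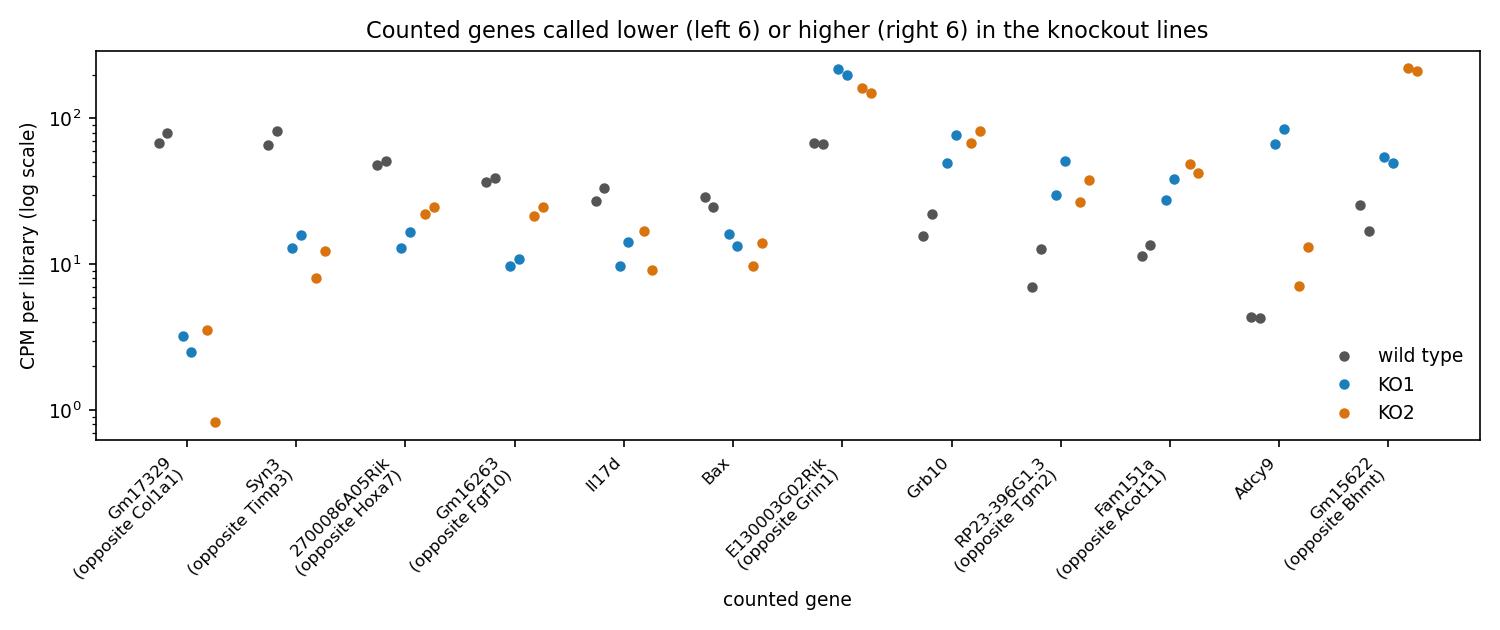
CPM (log scale) of 12 counted genes in each of the 6 libraries, a point per library, coloured by group. Gm17329 (opposite Col1a1) averaged 74.1 in wild type and 2.54 in the knockout lines, and Grb10 18.9 and 69.2, while Adcy9 averaged 75.9 in KO1 and 10.2 in KO2.

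By the symbol of the counted gene, few members of the gene lists changed in the lines together, and their counts describe the opposite strand or low counts of their own. Of the 15 measured imprinted genes, Grb10 rose and Copg2 (opposite Mest, -0.42 ± 0.05) and Rtl1 (opposite Mir433, -0.37 ± 0.08) fell. Of 4 formative and primed pluripotency genes, Lefty2, a Nodal antagonist gene, fell (-0.95 ± 0.24), and of 4 p53 targets the apoptosis gene Bax fell (-0.999 ± 0.26). Of 21 genes of class I histone deacetylases and their complexes, the histone-binding subunit gene Rbbp4 rose (opposite Gm17525, 0.69 ± 0.18), and of 12 Polycomb genes L3mbtl2 rose. Of 8 mitochondrial transcripts, mt-Cytb (0.48 ± 0.12) and mt-Nd4 (0.32 ± 0.09) rose. In the lines apart, Grb10 and mt-Cytb passed in both, Lefty2 in KO1, Copg2, Bax, Rbbp4 and L3mbtl2 in KO2, mt-Nd4 in neither (adjusted p 0.0627 and 0.0572), and Rtl1 in opposite directions. DESeq2 called Grb10, Copg2 and Rtl1 in the lines together, did not call Lefty2, Bax, Rbbp4, mt-Cytb or mt-Nd4 (adjusted p 0.155 to 0.345), and gave no adjusted p to L3mbtl2. Adjusted over the list alone, the calls were the same in number except for 2 formative genes lower, 1 neuroectoderm gene lower, 1 Hox gene lower and 3 mitochondrial transcripts higher.

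The values that follow are also for the symbol of the counted gene. Read as counts of the opposite strand, they do not show whether the listed genes' own transcripts changed. No member was called among 14 general pluripotency genes (Sox2 -0.04 ± 0.15, Trim28 -0.12 ± 0.17) or 14 naive pluripotency genes (Klf4 0.10 ± 0.12, Klf2 0.34 ± 0.16). The same held for 2 endoderm genes (Apoe 0.01 ± 0.21, Lamc1 0.21 ± 0.29) and 3 streak and mesoderm genes (Tbx6 -0.34 ± 0.24, Cdx1 -0.08 ± 0.32). It also held for 3 neuroectoderm genes (Pax6, opposite Elp4, 0.08 ± 0.10) and 3 trophoblast genes (Eomes -0.30 ± 0.395, and Tcfap2a, opposite Gm16989, 0.48 ± 0.58). It held for 4 germline genes (Sycp1 0.29 ± 0.17, Syce2 -0.21 ± 0.23), Hoxc13, the only Hox gene measured (-0.44 ± 0.17), and Zfp750, the only gene measured of the list for the 2-cell-like state (0.67 ± 0.52). Among chromatin genes, none was called of 11 for H3K36 methylation (Psip1, opposite Snapc3, 0.0012 ± 0.15, and Hdgf -0.27 ± 0.18) or of 18 for H3K27 acetylation (Kat5, opposite Rnaseh2c, -0.06 ± 0.18). None was called of 8 FGF response genes (Ier2 -0.16 ± 0.25) or 6 Wnt targets (Ccnd1, opposite Oraov1, 0.14 ± 0.19, and Notum, opposite 4732444A12Rik, 0.18 ± 0.25). Nor was any of 17 glycolysis genes (Pfkp, opposite Pitrm1, -0.17 ± 0.08, and Pkm2 0.01 ± 0.17) or 7 cholesterol synthesis genes (Sqle -0.05 ± 0.18). The same was true of 12 stress response genes (Slc7a11 0.16 ± 0.07, and Atf5, opposite Nup62, -0.14 ± 0.07) and 57 ribosomal protein genes (Rpl18, opposite Sphk2, -0.06 ± 0.10, and Rps26 0.08 ± 0.11). Neither of 2 fibroblast markers was called (Tagln, opposite Pcsk7, 0.19 ± 0.19, and Fn1, opposite Apol7d, 0.34 ± 0.24). No Y-linked gene was measured. By camera, 0 of 14 testable lists were called (smallest adjusted p 0.421), 1 had an unadjusted p under 0.05, and 0 were called with an estimated correlation (smallest adjusted p 0.943) or by fry (0.0981). The median, mean and camera direction did not share a sign for the deacetylase, H3K27 acetylation, glycolysis and stress response lists.

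By the symbol of the gene opposite, the lists gave 21 called entries among 86, 5 higher and 16 lower. Of 6 counted genes opposite fibroblast markers, 4 fell: Gm17329 (Col1a1), Syn3 (Timp3), 2810430I11Rik (Col5a1, -0.98 ± 0.27) and Gm15270 (Ctgf, -0.62 ± 0.10). Gm13372 (Col5a1, -1.15 ± 0.37) and Apol7d (Fn1, 0.04 ± 0.05) were not called, and adjusted over the list alone 5 were lower. The median was -1.06, and camera called this list alone among 10 (adjusted p 5.92e-05; adjusted p 0.188 with an estimated correlation); fry's adjusted p was 0.00736, and fry also called the Polycomb list (adjusted p 0.0431, against 0.868 by camera). In KO1 and KO2 apart, camera's adjusted p for it was 0.00345 and 1.13e-04 (adjusted p 0.350 and 0.204 with an estimated correlation). Of 2 counted genes opposite Hox genes, 2 fell, among them 2700086A05Rik (Hoxa7, on chromosome 6). In KO2, where chromosome 6 shifted by -0.02, 2700086A05Rik stood at -1.07 ± 0.24. Of 10 genes opposite imprinted genes, 4 fell, among them AF085738 (Gnas, -0.42 ± 0.04) and AL672259.1 (Nnat, -1.39 ± 0.27), with a camera adjusted p of 0.424. Of 5 genes opposite Polycomb genes, Gm16706 (Suz12, on chromosome 11) rose by 0.59 ± 0.05 and Gm17629 (Ezh2, on chromosome 6) fell (-0.38 ± 0.06), and Gm13061, opposite the pluripotency gene Lin28a, fell (-0.43 ± 0.08). In the lines apart, AL672259.1 and Gm17629 passed in KO1 and not in KO2 (adjusted p 0.427 and 0.143), and 2810430I11Rik in KO2 and not in KO1 (adjusted p 0.0939).

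In KO1 against wild type, Gm17232 (chromosome 14, 64112536 to 64118709), opposite the threonine dehydrogenase gene Tdh, fell from 3956 to 1749 CPM (-1.18 ± 0.05, adjusted p 2.99e-17). 2410003K15Rik (opposite the RNA-binding protein gene Igf2bp3, -1.16 ± 0.06) and Loxl3 (opposite the protease gene Htra2, -1.03 ± 0.08), both on chromosome 6, fell, as did AF085738 (opposite Gnas, -0.63 ± 0.05) and Gm15441 (opposite Txnip, -0.82 ± 0.07). AL672259.1, opposite the imprinted gene Nnat, fell from 36.1 to 4.10 CPM (-3.10 ± 0.38), and Gm16989, opposite the transcription factor gene Tcfap2a, from 39.7 to 6.96 (-2.49 ± 0.34). Nefm, opposite the neurofilament gene Nefl, rose from 59.5 to 175 CPM (1.55 ± 0.15). These genes were chosen after their values were seen, and the largest of their adjusted p by edgeR's quasi-likelihood test was 4.15e-06, for Gm16989. In all, 174 genes rose and 319 fell, 64 of the latter on chromosome 6. DESeq2 called 207 genes, the test against a log2 change of 0.5 called 74, and leaving out KO1 replicate 1 or 2 gave 280 or 303. Of the lists by the counted gene's symbol, camera called 0 of 14 (1 at an unadjusted p under 0.05; 0 by fry), and the imprinted genes, 5 of 15 higher, had an adjusted p of 0.0554.

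In KO2 against wild type, Gm15622, opposite Bhmt, rose from 21.2 to 216 CPM (3.35 ± 0.18, adjusted p 4.41e-14). On chromosome 11, Gm16706 (opposite the Polycomb gene Suz12, 0.85 ± 0.05), Gm11670 (opposite the Wnt target gene Axin2, 1.05 ± 0.07), Gm16033 (opposite Adam19, 1.54 ± 0.10) and Gm11532 (opposite the transcription factor gene Sp6, 1.43 ± 0.09) rose, each with an adjusted p of 1.54e-12. Copg2, opposite the imprinted gene Mest, fell from 934 to 519 CPM (-0.85 ± 0.06). In the imprinted cluster of chromosome 12, Rtl1 (-1.16 ± 0.10) and Gm17639, opposite Meg3 (-0.64 ± 0.12), fell, with adjusted p of 6.57e-10 and 2.93e-04 by edgeR's quasi-likelihood test. These genes were chosen after their values were seen. In all, 252 genes rose, 123 of them on chromosome 11, and 200 fell. DESeq2 called 170 genes and the test against a log2 change of 0.5 called 59. Of the lists by the counted gene's symbol, camera called 0 of 14 (1 at an unadjusted p under 0.05; 0 by fry).

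KO1 and KO2 differed from each other in more genes than either did from wild type: 399 were higher in KO1 and 572 higher in KO2. Adcy9 was higher in KO1 (2.87 ± 0.27, adjusted p 2.34e-09). Lgi1 and the adrenergic receptor gene Adra1a held 22 counts each in KO1 and 0 in KO2, at least 7.05-fold higher over the floor of 3 counts. Tmem40 held 24 and 1 (ratio 23.1, 95% interval 3.76 to 948), and the zinc finger gene Zfp462 26 and 3 (8.33, 2.55 to 43.0). Higher in KO2 were Foxd1 and Vax2os1, each at 26 counts against 3 (9.02, 2.76 to 46.5), the homeobox gene En2 at 23 against 3 (7.98, 2.41 to 41.5), Ceacam16 (opposite RP23-191I16.2, -2.83 ± 0.38) and Gtf2ird2 (opposite Ncf1, -2.38 ± 0.42). The adjusted p by edgeR's quasi-likelihood test of the named genes ran up to 0.00973, for En2. DESeq2 called 417 genes and gave no adjusted p to Foxd1, Lgi1, Adra1a, Tmem40, Zfp462, Vax2os1, En2, Ceacam16 or Gtf2ird2, and leaving out KO1 replicate 1 or 2 gave 561 or 643. The 57 ribosomal protein genes lay lower in KO1 than in KO2 (median -0.24; camera adjusted p 0.0473; adjusted p 0.751 with an estimated correlation).

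In both lines, 31 genes rose and 48 fell, among them Grb10, E130003G02Rik, Gm16033, Gm17329, Syn3 and 2700086A05Rik, against 8.71 and 12.7 for independent lists of these sizes. A further 40 genes were called in opposite directions, among them Gm17232 (opposite Tdh, -1.18 in KO1 and 0.29 in KO2), Nefm (1.55 and -0.64), Gm15401 (opposite the transcription factor gene Tcf7l1, 0.66 and -0.71), Gm16764 (opposite Nkx1-2, -0.61 and 0.69), Rtl1 (0.42 and -1.16) and Tlcd1 (opposite Rpl23a, -0.24 and 0.46). No number for independent lists was computed for opposite directions, so the excess in the same direction does not by itself show a shared effect. Across genes, which are not independent replicates, the log2 fold changes of the lines correlated at 0.313 with 57.6% of the same sign. Unchanged groups simulated against the same wild type libraries gave 0.507, 67.0% and 0 genes called in both. The covariance was 0.0948 against a simulated 0.0570, a difference of 0.0378. With KO1 set against wild type replicate 1 and KO2 against replicate 2, in a split chosen after these values were seen, the correlation was 0.0405. The other way round, it was 0.110. In these splits, 51.05% and 51.59% of the genes had the same sign in both lines. Each line then stood against a single wild type library, and part of the overlap of 79 may come from the shared libraries. Without KO1 replicate 2 the count of 79 was 52.

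**Figure D3:**
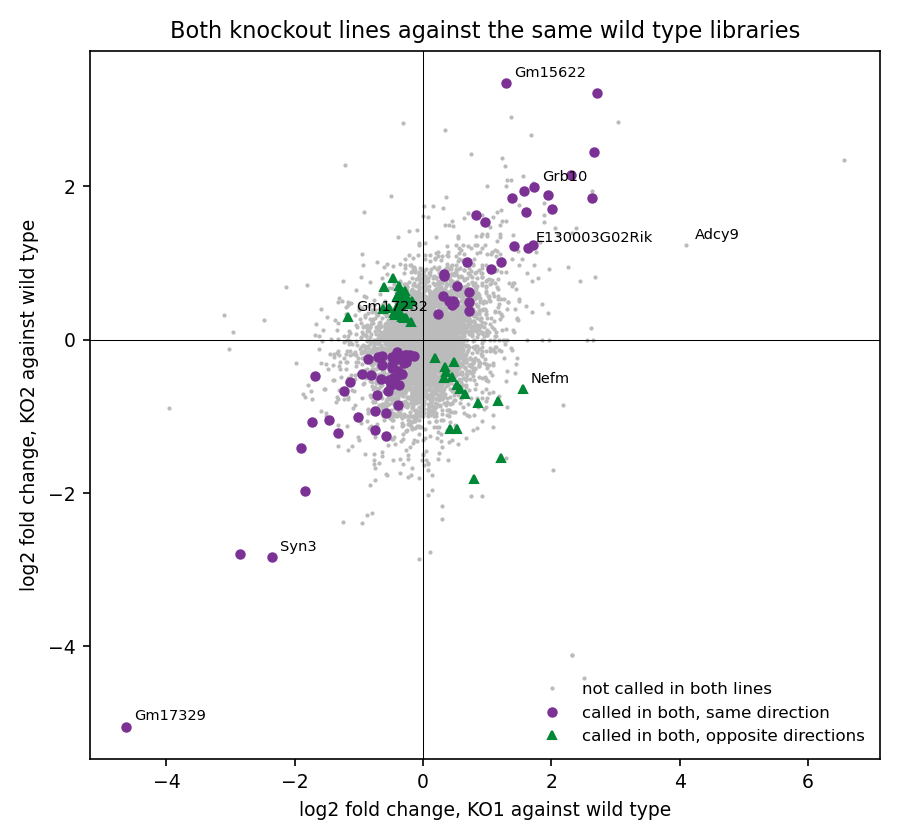
Log2 fold change of each of 5034 genes in KO1 (x axis) and KO2 (y axis) against the same wild type libraries. Circles mark the 79 genes called in both lines in the same direction, triangles the 40 called in opposite directions, and grey points the rest; Gm17329 lies at -4.64 and -5.05.

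Counts on whole chromosomes differed between the lines. Genes on chromosome 6 lay lower in KO1 (shift of the median -0.42 over 259 genes; -0.41 and -0.42 in the libraries), with 18.9% of them above 0, and at -0.02 in KO2. Genes on chromosome 11 lay higher in KO2 (0.41 over 560 genes; 0.40 and 0.40 in the libraries), with 83.8% of them above 0, and at 0.06 in KO1. By camera, in tests chosen after the shifts were seen, the adjusted p was 5.39e-15 for chromosome 6 in KO1 and 1.65e-22 for chromosome 11 in KO2 (adjusted p 0.0214 and 0.00305 with an estimated correlation). Without these chromosomes, 211 genes were called in the lines together. The 16 mitochondrial genes lay higher in KO2 (0.37; 0.45 and 0.29 in the libraries; camera adjusted p 0.0490, adjusted p 0.571 with an estimated correlation) and at 0.29 in KO1, while the wild type libraries stood 0.20 above and -0.20 below their mean. Without wild type replicate 1 the shift in KO2 was 0.52, and without replicate 2 it was 0.17.

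**Figure D4:**
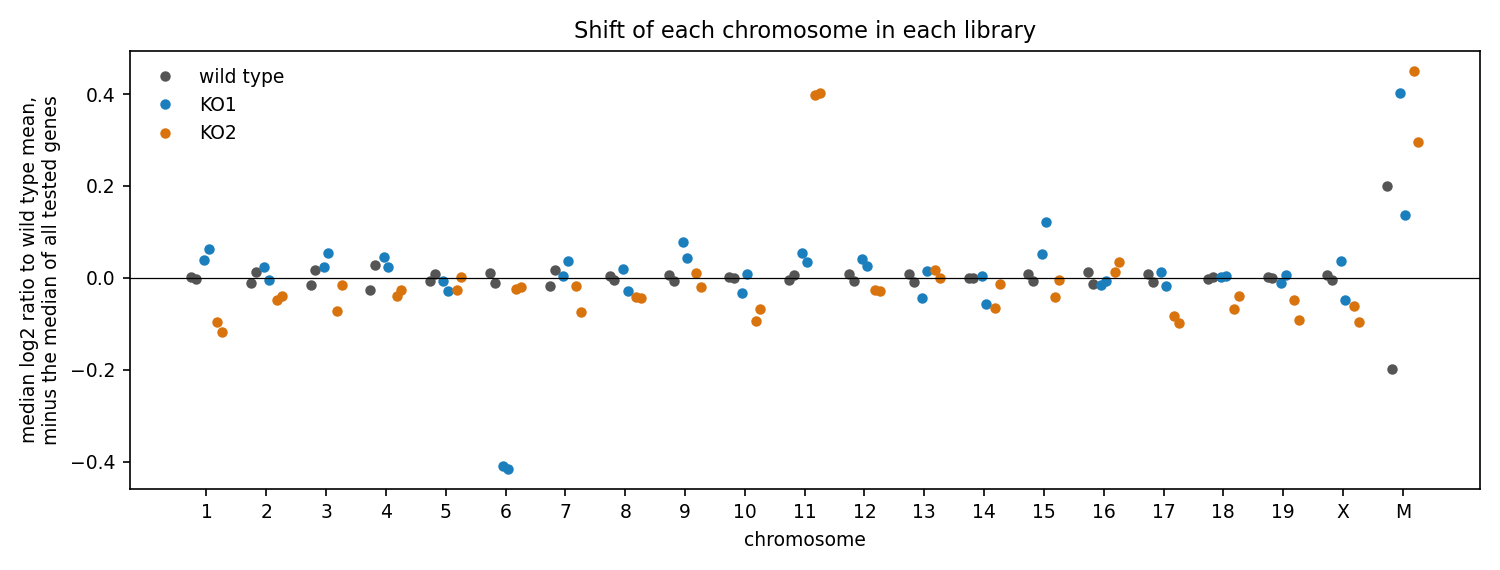
Median log2 ratio to the wild type mean of the genes on each chromosome, minus that of all tested genes, a point per library, coloured by group. Both KO1 libraries lie at -0.41 and -0.42 on chromosome 6 and both KO2 libraries at 0.40 on chromosome 11, while the wild type libraries lie at 0.01 and -0.01 on both.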

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

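The tests chosen only after the result was seen were that of the share of counts at ribosomal protein genes, that of each chromosome's shift in the other line, that of the number of genes opposite fibroblast markers that were lower in both lines, and the camera tests of chromosomes.

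The knockout lines differed from each other in 971 genes by edgeR's quasi-likelihood test of the difference, and 40 genes called in both lines went in opposite directions; of these 40, 14 lie on chromosome 11, all 14 lower in KO1 and higher in KO2. The test of the difference also set apart Adcy9 (log2 difference 2.87, higher in KO1), Lgi1 and Adra1a (each at least 7.05-fold higher in KO1 over the floor of 3 counts), Tmem40 (ratio 23.1) and Zfp462 (ratio 8.33). Higher in KO2 were Foxd1 (ratio 9.02), Vax2os1 (9.02), En2 (7.98), Ceacam16 (log2 difference -2.83, opposite RP23-191I16.2) and Gtf2ird2 (-2.38, opposite Ncf1).

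The shift between KO1 and KO2 was -0.43 on chromosome 6 and -0.33 on chromosome 11, with camera adjusted p of 6.28e-09 and 2.14e-10 (adjusted p 0.0245 and 0.00989 with an estimated correlation). The tables argue against a few abundant genes or the scaling, since the less abundant genes of each chromosome shifted by at least 0.365 in size, and against loss of NSD1 alone, since chromosome 6 shifted by -0.018 in KO2 and chromosome 11 by 0.06 in KO1. A whole-chromosome copy number difference may be the source: with each chromosome split into 5 parts of equal gene number, in 10 of 10 parts the median shifted the same way by at least 0.265. The shares of cells or the copies involved were not measured, and whether such a difference followed the loss of NSD1 in a line remains open.

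The abundant transcript Rpl23a held 29 to 46 counts per library, and Tlcd1 opposite it 11382 to 18509. Libraries that do not mark strand are argued against by the ribosomal protein genes, which held at most 0.231% of the counts of a library. Counting on the strand opposite to each gene may be the source: counted genes that share the same gene opposite correlated at 0.634 (87 pairs, 95% interval 0.417 to 0.764) in their difference between KO1 and KO2, against 0.138 for neighbours with different genes opposite (1333 pairs). Pairs with the same gene opposite lie at the same locus, while neighbours may lie further apart. The contrast therefore does not separate strand from locus, and it was not computed without chromosomes 6 and 11. Whether a small share of each gene's own fragments was counted too cannot be told: a counted gene and the less abundant gene opposite it correlated at 0.276 (169 pairs, 95% interval 0.134 to 0.407), and at 0.108 without chromosomes 6 and 11. The pairs are genes of the same libraries and are not independent replicates.

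By direction alone, counted genes opposite collagen and other fibroblast markers lay lower in both knockout lines for 5 of 6 members. These were Gm17329 (Col1a1), Syn3 (Timp3), Gm15270 (Ctgf), 2810430I11Rik and Gm13372 (both Col5a1). By edgeR's test, 3 of the 6 were called lower in KO1 and 5 in KO2. Fibroblast RNA in the wild type libraries may be a source, although the labels name gelatin and no feeder cells; over the 2 members opposite other markers the median was -0.16 in KO1 (SD 0.33) and -0.42 in KO2 (SD 0.61). In KO1 this lay 0.338 above the bound of -0.5 set beforehand, which would argue against fibroblast RNA, but the bound was judged wrong after the value was seen: 1 of the 2 members, Apol7d, opposite the fibronectin gene Fn1, stood at 1181 CPM in wild type and 1215 in the lines, a level that would hide a small share. In the knockout lines 5 of the 6 members held at least 5 CPM, and the source of those counts was not tested. Loss of NSD1 in the ES cells stays open as well, since 5 of 6 lower in both lines would follow from either, and the sources cannot be told apart with 2 wild type libraries.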

How the results depend on the processing

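The alternatives without AY036118, without chromosomes 6 and 11, with only genes opposite another gene's exons, with lists matched by the opposite gene, and with each line against 1 wild type library were chosen after the results were seen; the rest were fixed earlier. Of 91 named genes, with a gene named in 2 comparisons counted in each, 55 were called in the comparison that named them, and none of these changed sign in any alternative; in all, 1267 pairs of a gene and an alternative kept direction and side of the threshold, 240 lost the call (34 of them given no adjusted p by DESeq2), 2 gained it and 34, none of a called gene, changed sign. Counts of called genes stayed within 1.5 times under DESeq2 size factors, no filter, a mean CPM of at least 1, limma-voom, without AY036118 and with only genes opposite exons.

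For the lines together (333 genes), DESeq2's Wald test called 115, the test against a log2 change of 0.5 called 16, the knockout libraries as a single group 6, the line as a random block 5 and the fit without chromosomes 6 and 11 211. Those 6 and 5 follow from counting the difference between the lines as spread. In the fit without chromosomes 6 and 11, 228 of the 333 genes were still tested, and 205 of these were called in the same direction. The cause of the DESeq2 difference was not tested, though DESeq2 gave no adjusted p to 43 of the 333. For KO1, DESeq2 called 207 and the test against 0.5 called 74; for KO2 these were 170 and 59; between the lines DESeq2 called 417. Leaving out each library in turn gave 213 to 362 genes for the lines together, 280 to 591 for KO1, 328 to 435 for KO2, 561 to 1065 between the lines, and 52 to 66 called in both lines, with a lone library assumed to vary like the other groups; these fits rest on fewer samples. With KO1 against wild type replicate 1 and KO2 against replicate 2, 26 genes were called in both lines, and 39 the other way round, with fewer called in each line (266 to 323). The lowest counts came without wild type replicate 1 (213), without KO1 replicate 1 (280 and 561) and without KO1 replicate 2 (52). The list tests gave 0 to 1 called list without a library, the mitochondrial transcripts without wild type replicate 1 (camera adjusted p 0.0143; adjusted p 0.819 with an estimated correlation), and 1 with lists matched by the opposite gene.

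Values that passed no test crossed 0 when a library was left out: Sox2 (-0.10 to 0.0067), Klf4 (-0.018 to 0.23), Zfp750 (-0.16 to 1.06), Apoe (-0.19 to 0.24), Lamc1 (-0.087 to 0.43), Cdx1 (-0.26 to 0.086), Syce2 (-0.56 to 0.27), Psip1 (-0.093 to 0.11), Kat5 (-0.21 to 0.062), Ier2 (-0.38 to 0.010), Pkm2 (-0.20 to 0.18), Sqle (-0.19 to 0.11), Rpl18 (-0.12 to 0.017), Rps26 (-0.029 to 0.18) and Hdac1 (-0.20 to 0.38). Cdx1 was at 0.0076 with the knockout libraries as a single group. Psip1 was at -0.0034 with no filter, -0.0093 with a mean CPM of at least 1, -0.0027 with limma-voom and -0.0013 with the line as a random block. Pkm2 was at -0.0084 with limma-voom and -0.011 with the random block. The cause was not tested.

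With the replicate number as a block, 321 genes were called for the lines together, 482 for KO1, 416 for KO2 and 935 between the lines, and Psip1 was at -0.00082. Deviations of libraries with the same number from their group means correlated at 0.011, -0.0069 and -0.036. At such low counts this cannot exclude a pairing by number. In each group replicate 1 had the higher mitochondrial share of counts (wild type 0.4222% against 0.3165%, KO1 0.5225% against 0.4248%, KO2 0.4601% against 0.3833%). AY036118 took the smaller share in replicate 1 of each group, while the ribosomal protein share did not go the same way in all groups. At a median of 23 to 27 counts per tested gene, 66% of simulated log2 changes of 1 were called for the lines together.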

Other observations

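The lists by the gene opposite and the fit without chromosomes 6 and 11 were chosen only after the results were seen, as were the genes described here, while the lists by the counted gene's symbol and the contrasts were planned.

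By the counted gene's symbol, counts at 5 of 15 imprinted genes rose in KO1: Grb10 (1.73), the peptidase gene H13 (opposite Gm17559, 0.73), Commd1 (opposite Zrsr1, 0.67), Gnas (opposite AF085738, 0.62) and Rtl1 (0.42), with edgeR adjusted p of 2.38e-05 to 0.0285. Gnas held 69 to 191 counts per library, against 3392 to 5087 for AF085738, which fell in KO1 as given above. Read as counts of the opposite strand, these values do not show that the imprinted genes' own transcripts rose. In KO2, Grb10 rose (1.98) while Copg2 (opposite Mest, -0.85) and Rtl1 (-1.16) fell. Between the lines 6 of the 15 were called higher in KO1 and 1 lower, and the list was not called, with a camera adjusted p of 0.0746 (adjusted p 0.751 with an estimated correlation) and a fry adjusted p of 0.0579. By the gene opposite, 3 of 10 were called higher in KO1 and 3 lower (camera adjusted p 0.816). In the lines together, camera called the imprinted list by the gene opposite lower without chromosomes 6 and 11 (adjusted p 0.0415; adjusted p 0.258 with an estimated correlation) and not with them (adjusted p 0.424; 0.849 with an estimated correlation).

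Among genes opposite members of other lists, 3 of 3 opposite Wnt target genes rose in KO2. Gm11670 (Axin2, 1.05) and 4732444A12Rik (Notum, 0.81) were among them, and both lie on chromosome 11, whose genes shifted by 0.41 in KO2. In KO1, Gm12868 (opposite the glucose transporter gene Slc2a1, -0.43), Gm17327 (opposite the glycolytic enzyme gene Gpi1, -0.26) and Csnk1d (opposite the lactate transporter gene Slc16a3, -0.47) fell, and Csnk1d, on chromosome 11, rose in KO2 (0.81). Gm17629, opposite the Polycomb gene Ezh2 on chromosome 6, fell in KO1 (-0.60), where that chromosome shifted by -0.42. 4632419I22Rik, opposite the Mediator gene Med13 on chromosome 11, rose in both lines (0.31 and 0.56), and Gm13061, opposite Lin28a on chromosome 4, fell in both (-0.48 and -0.38). All of the counted genes given by name here passed edgeR's quasi-likelihood test in the line named, with adjusted p up to 0.00798.

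On the first principal component of log2 CPM (38.8% of the variance), both KO1 libraries lay at one end (20.3 and 19.6), both KO2 libraries at the other (-20.5 and -19.5), and the wild type libraries between them (-0.665 and 0.751). The second (24.5%) set the wild type libraries (18.8 and 17.9) apart from the 4 knockout libraries (-9.63 to -8.75). With AY036118 included, libraries of a group differed by 1.35 to 1.82 times sampling noise (chi-square per degree of freedom) and libraries of different groups by 3.05 to 5.58 times. The values were not computed without AY036118, whose share of the counts differed between libraries.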
